A study of Mus musculus with 12 samples.

How the data were processed

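RNA sequencing measured transcripts in 12 libraries of cultured mouse bone marrow cells, in 6 groups of 2 libraries. Per the labels, the cells came from C57BL/6 mice and were grown in IMDM with 15% FBS and with IL3, IL6 and SCF at 10 ng/ml each. They were collected after 10 days of drug selection, with G418 and puromycin in the cotransductions and with puromycin alone in the MLL-AF9 stable cells. RNA was extracted with Trizol, purified on a Qiagen column and made into TruSeq v2 libraries with oligo(dT) priming.

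The authors deposited 3 tables of FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), 1 per experiment, with a value for each gene symbol in each library. The labels name Bowtie2 2.0.0.7, TopHat2 2.0.3, Cuffdiff (version not given in the sources used here) and the mm9 build as the tools and genome behind them. The gene annotation, the scaling between libraries and any filter are not given in the sources used here. The values fit FPKM: they run in decimals from 0, each library sums to a different total, and low values within a group move in steps that depend on the gene. The tables held 23309, 23235 and 23235 entries for the MLL-AF9 cotransduction, the E2A-HLF cotransduction and the stable cells, and 22364 symbols were in all 3 tables. A spreadsheet had turned 27, 25 and 25 symbols into dates, and these entries were tested but not named. Genes are given by symbol alone, since the tables carry no other identifier, and no coordinates are given because the annotation at hand is of another build.

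No read counts are in the tables, so the total depth of the libraries is unknown and no counting interval or detection floor was computed. The steps between low values give relative depth within a group, since 84.7% to 87.4% of the ratios between replicates were ratios of whole numbers up to 6 (within 0.5%) after 1 factor. By this factor, replicate 2 had 1.63 times the depth of replicate 1 in the PRDM16 group of the MLL-AF9 cotransduction, and 0.916 to 1.17 times in the other 5 groups. The FPKM of a library summed to between 570872 and 683269, which reflects scaling and transcript lengths rather than depth. The 10 most abundant genes held 6.46% to 12.9% of that sum.

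Each table was fitted alone, with values as log2 of FPKM plus a pseudocount of 1, in R 4.3.3 with limma 3.58.1 (linear model, moderated variance with a trend on mean level, two-sided). The contrast was PRDM16 minus PRDM16mut, 2 libraries against 2. Genes with an FPKM of at least 1 in at least 2 of the 4 libraries were tested, which left 11071, 11010 and 10580 genes. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in its table. The p-values rest on the variance that limma shares across genes, because an exact permutation test of 2 against 2 cannot go below 0.333. They measure only the spread between these libraries, which may be technical, since the labels do not say whether the 2 replicates of a group were separate cultures. Fold changes on this scale understate the change of genes with a low FPKM.

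The comparisons, the tests, 21 gene lists and the rule for naming genes were fixed before the data were examined. The lists cover the Hoxa cluster, MLL fusion targets outside it, blood stem and progenitor cells, erythroid, megakaryocyte, neutrophil, monocyte, mast cell, B cell and T or NK cell markers, MHC class II, stromal cells, cell division, Myc and ribosome biogenesis, interferon response, p53 targets, TGF-beta signalling, antioxidant genes, brown fat, inflammatory cytokines and immediate early genes. Lists with at least 3 tested members were tested with camera in limma at a preset correlation between genes of 0.01, adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry, which asks whether a list's genes move on balance 1 way without comparing them with other genes, were run beside it. With an estimated correlation camera takes its degrees of freedom from the residuals, which are few with 2 libraries per group. A list can then lose its call whatever its correlation. The genes named for each comparison are Prdm16, Gfi1b, Hoxa9 and Meis1, the 8 with the largest and the 8 with the smallest log2 fold change among called genes whose groups do not overlap, and up to 4 members of smallest p from each list that was called or had at least 2 called members. Clone names, predicted genes and small RNAs were passed over in the top genes. For each of the difference tests the 5 largest differences in each direction are named, and for genes called the same way in all 3 comparisons the 8 of largest mean change.

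Differences between experiments in the effect of PRDM16 were tested with limma in 1 fit of all 12 libraries with 6 groups, as a contrast of contrasts, over 9488 genes that passed the filter in every table. Overlaps of called genes were tested with Fisher's exact test, two-sided, 12 tests adjusted together. The procedure was tested on simulated data with noise set by the trend of spread with FPKM level in each table. Of 50 genes changed 1.5-fold, 90%, 96% and 94% were recovered in the MLL-AF9 cotransduction, the E2A-HLF cotransduction and the stable cells, with 6, 8 and 9 calls among 10871, 10810 and 10380 genes left as they were. For the difference of effects, 50 of 50 genes changed 1.5-fold were recovered, with 14 calls among 9338 others. Camera found 20 of 20 simulated lists moved 1.5-fold and 0 of 20 lists not moved in each experiment. The simulated genes varied independently and most were left unchanged. Their spread differed less from gene to gene than in the real libraries, where limma's prior had 3.21, 3.81 and 3.48 degrees of freedom. For the difference of effects and for camera every gene had the spread of the trend, and the lowest mean levels were raised. The simulation therefore does not test lists of correlated genes, tables where many genes change or a spread as uneven as the real one. The highest estimated correlation, of the MHC class II list in the MLL-AF9 cotransduction, was 0.88.

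The alternatives were pseudocounts of 0.1 and 0.5, no filter on low values, an FPKM of at least 5, quantile normalization, median-ratio scaling, a robust prior, no trend in the prior, a replicate block, summing of repeated symbols, the spread shared over all 12 libraries, a minimum change of 2-fold, an adjusted p under 0.01 for overlaps, and leaving out each library in turn. The shared spread was run over the 9488 genes that passed the filter in every table, so the genes and list members tested changed along with the spread. A further setting without small RNAs was added after the data were seen. Figures were drawn with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9. No library was left out of the results given.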

Results

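The data are RNA-sequencing profiles of mouse bone marrow cells that carry a leukaemia fusion oncogene together with PRDM16 or with a mutant form of it, PRDM16mut. PRDM16 is a zinc finger protein with a PR domain, and the series title names it as a histone methyltransferase in tumor suppression. The labels do not say which change PRDM16mut carries. In the MLL-AF9 cotransduction and the E2A-HLF cotransduction, lineage-negative bone marrow cells received the fusion oncogene and PRDM16 or PRDM16mut together. In the MLL-AF9 stable cells, bone marrow cells already transduced with MLL-AF9 received PRDM16 or PRDM16mut. MLL-AF9 and E2A-HLF are fusion transcription regulators found in human leukaemias. Each of the 6 groups had 2 libraries, and the summed FPKM ran from 570872 to 683269 per library. Read counts are not given in the sources used here, so the total depth is unknown. Steps between low values put replicate 2 of the PRDM16 group of the MLL-AF9 cotransduction at 1.63 times the depth of replicate 1, and the other pairs at 0.916 to 1.17. The design asks, for each of the 3 experiments, which genes differ between cells with PRDM16 and cells with PRDM16mut. This difference is called the effect of PRDM16 below. No group without either form is among the 12 libraries. A gene said to rise or fall with PRDM16 may therefore have been moved by PRDM16, by PRDM16mut or by both.

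In the MLL-AF9 cotransduction, cells with PRDM16 held almost no Hoxa9 transcript, a homeobox gene that MLL fusions activate. Its FPKM was 0.0996 ± 0.00562 (SD, n = 2) with PRDM16 and 30.2 ± 0.298 with PRDM16mut. Of the neutrophil granule genes tested 19 of 20 fell, and of the mast cell, basophil and eosinophil genes 12 of 14. Among them was Chi3l3, a chitinase-like secreted protein, at 2.64 ± 0.0110 against 3348 ± 5.18 FPKM. Of the genes of MHC class II antigen presentation 7 of 8 rose, with Cd74, the invariant chain, at 937 ± 56.6 against 29.5 ± 0.813 FPKM. Gfi1b, a zinc finger repressor of the erythroid and megakaryocyte lineages, rose from 3.89 ± 0.0216 to 17.99 ± 2.44 FPKM, a log2 fold change of 1.95 (limma, Benjamini-Hochberg adjusted p = 4.94e-05). None of these 3 lists passed with the correlation between genes estimated (camera in limma, adjusted p = 0.198 or more). With 2 libraries per group this form of the test has few degrees of freedom, so the loss alone does not show a high correlation.

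Prdm16 itself measured 83.9 and 119 FPKM in the PRDM16 libraries against 29.5 and 30.1 in the mutant libraries, a log2 fold change of 1.71 (limma, Benjamini-Hochberg adjusted p = 4.18e-04). The tables do not separate transcripts of the introduced copy from those of the cells' own gene. Hoxa9 changed by -4.83 on the log2 scale with a standard error of 0.0574 (adjusted p = 9.12e-07). Meis1, the homeobox partner of Hoxa9, went the other way and rose by 1.10 (10.99 ± 0.552 against 4.60 ± 0.271 FPKM, adjusted p = 1.06e-04). In all, 7698 of 11071 genes tested passed (69.5%), 3936 higher and 3762 lower with PRDM16, and 1720 of them changed at least 2-fold. The median absolute log2 fold change of the called genes was 0.55. The FPKM of the 2 groups did not overlap for 86.3% of genes, where chance gives 33.3%.

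**Figure D1:**
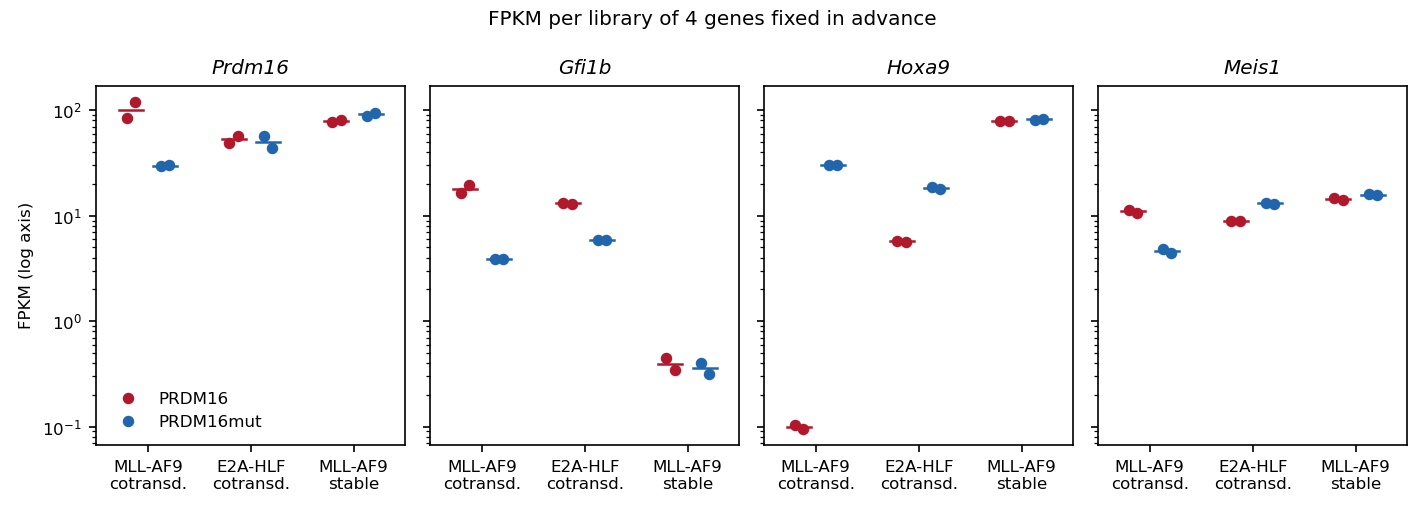
FPKM of Prdm16, Gfi1b, Hoxa9 and Meis1 in each of the 12 libraries on a log axis, with points for libraries and bars for the mean of 2, red for PRDM16 and blue for PRDM16mut. Hoxa9 lies at 0.0996 FPKM with PRDM16 and at 30.2 with PRDM16mut in the MLL-AF9 cotransduction, and at 78.8 and 82.1 in the stable cells.

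The genes that rose most in the MLL-AF9 cotransduction were Ctsj, a cathepsin (log2 fold change 5.98, 199 against 2.16 FPKM, adjusted p = 7.97e-07 by limma), Hba-a2, Pdcd1, the PD-1 receptor (5.08), Cd74 (4.94), Npy, a neuropeptide (4.85), Id3, an inhibitor of helix-loop-helix factors (4.54), H2-Aa (4.46) and Selp, P-selectin (4.23). Hba-a2, an alpha globin gene, had a log2 fold change of 5.51 but shares its reads with Hba-a1, and the tables assign them to either copy. The sum of both was 271 and 249 FPKM with PRDM16 and 30.2 and 29.1 with PRDM16mut, a ratio of 8.78, and the call on Hba-a2 alone was lost when either PRDM16 library was left out. The genes that fell most, after Rn45s, were Chi3l3 (-9.85), Ngp (-8.38), Cma1, a mast cell chymase (-8.22), Mcpt4, another (-8.17), Camp (-7.97), Stfa2, a stefin (-7.60), and Elane, neutrophil elastase (-7.51, 13.7 against 2676 FPKM). Rn45s, the ribosomal RNA precursor, was listed at 0 in both PRDM16 libraries and at 1542 and 1554 FPKM in the mutant libraries, so no fold is given. It measured from 941 to 1451 FPKM in the other 8 libraries, which come from separate tables. Whether the 2 PRDM16 libraries were processed like the mutant libraries, for instance in the masking of ribosomal RNA, is not given in the sources used here. A difference in processing would fall together with the difference between the groups.

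Among genes of blood lineages in the MLL-AF9 cotransduction, the neutrophil granule list fell furthest. Of its 20 tested members, 19 fell and 1 rose, with a median log2 fold change of -4.60 (camera in limma, Benjamini-Hochberg adjusted p = 2.74e-11, and adjusted p = 0.198 with an estimated correlation). Chi3l3, Ngp, Camp and Elane had the smallest p-values. The list of mast cells, basophils and eosinophils had 12 members lower and 1 higher of 14, with a median of -3.78 (adjusted p = 6.02e-07, and adjusted p = 0.198 with an estimated correlation). Tpsb2, a tryptase, changed by -7.05 and Fcer1a, a chain of the IgE receptor, by -6.12. Erythroid genes moved the other way, 12 higher and 1 lower of 13, with a median of 1.63 (adjusted p = 7.80e-04, and adjusted p = 0.198 with an estimated correlation). Car2, a carbonic anhydrase, rose from 5.83 to 42.2 FPKM, and the erythroid regulator Tal1 and the membrane protein Rhag rose by 1.82 and 2.34 on the log2 scale. Monocyte and macrophage genes were 12 higher and 5 lower of 18, with a median of 0.83 (adjusted p = 0.0410, and adjusted p = 0.291 with an estimated correlation). Csf1r, the receptor of macrophage colony-stimulating factor, rose from 11.9 to 63.7 FPKM, Ctss rose by 2.14 and Mpeg1 by 1.75, while F13a1 changed by -2.83. The monocyte call was lost without replicate 1 of the PRDM16 group (adjusted p = 0.0641), at an FPKM of at least 5 (0.134) and after quantile normalization (0.0526). With the spread shared over all 12 libraries, where fewer members pass the filter, the erythroid call was lost (0.113).

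MHC class II genes were 7 higher and 0 lower of 8 in the MLL-AF9 cotransduction, with a median log2 fold change of 3.004 (camera in limma, adjusted p = 1.03e-04, and adjusted p = 0.329 with an estimated correlation). H2-Ab1 and H2-Eb1, chains of the class II molecules, rose by 4.23 and 4.01. The megakaryocyte list was 7 higher and 5 lower of 12, with a median of 0.52 (adjusted p = 0.499), Selp and the thrombin receptor F2r (1.15) among the first and Gp1ba (-1.03) among the second. The T and NK cell list had 2 members higher and 1 lower of 4, with a median of 0.57 (adjusted p = 0.308), and Gzmb, granzyme B, rose from 171 to 485 FPKM. Only 2 members each of the B cell and stromal lists passed the expression filter, too few for a list test, with 1 B cell member and both stromal members, Vcam1 (-1.88) and Acta2 (-1.41), lower.

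All 7 tested genes of the Hoxa cluster fell in the MLL-AF9 cotransduction, with a median log2 fold change of -3.14 (camera in limma, adjusted p = 3.20e-05, and adjusted p = 0.198 with an estimated correlation). Hoxa10 changed by -4.49, Hoxa5 by -3.42 and Hoxa7 by -3.14. Other targets of MLL fusions were 2 higher and 9 lower of 12, with a median of -0.65 (adjusted p = 0.0223, and adjusted p = 0.329 with an estimated correlation). Runx2, Mef2c and Lmo2, transcription regulators of blood and bone cells, changed by -2.01, -1.40 and -1.33. Without a filter on low values this list did not pass (adjusted p = 0.175). Stem and progenitor genes were 9 higher and 4 lower of 14, with a median of 1.16 (adjusted p = 0.0830, and 0.0262 without a filter on low values). Mycn, Procr and Ly6a rose by 2.28, 1.85 and 1.41, and Kit, the receptor of stem cell factor, went from 47.1 to 5.68 FPKM, a change of -2.85.

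Cell division genes all fell in the MLL-AF9 cotransduction, 25 of 25, with a median log2 fold change of -0.71 (camera in limma, adjusted p = 1.34e-07, and adjusted p = 0.198 with an estimated correlation). The proliferation marker Mki67 measured 16.9 against 49.7 FPKM, and the mitotic genes Kif11, Top2a and Bub1 changed by -1.22, -1.07 and -1.22. The p53 target list was 13 higher and 3 lower of 17, with a median of 0.87 (adjusted p = 0.00279, and adjusted p = 0.250 with an estimated correlation). Cdkn1a, an inhibitor of cell cycle kinases, rose from 108 to 206 FPKM and Btg2, an antiproliferative gene, from 12.5 to 31.2, and Perp and Zmat3 rose by 1.54 and 0.99 on the log2 scale. The Myc and ribosome biogenesis list was 4 higher and 6 lower of 18, 4 and 5 when adjusted over the list alone, with a median of -0.14 (adjusted p = 0.499), with Rrp9 (0.51) and Fbl (0.42) higher and Rrp12 (-0.41) lower.

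The interferon response list was 16 higher and 2 lower of 21, 16 and 3 when adjusted over the list alone, with a median log2 fold change of 0.78 (camera in limma, adjusted p = 0.00122, and adjusted p = 0.198 with an estimated correlation). Rsad2, Ifi27l2a, Oasl2 and Ifit3, genes that interferon induces, rose by 2.37, 2.20, 1.70 and 1.54. With the spread shared over all 12 libraries, where only 12 members pass the filter with a median of 0.42, the interferon call was lost (camera adjusted p = 0.111). The immediate early list, which also responds to cell and RNA handling, was 12 higher and 1 lower of 14, with a median of 0.91 (adjusted p = 0.00119, and adjusted p = 0.329 with an estimated correlation), led by Atf3 (2.29), Nr4a1 (1.60), Klf2 (1.71) and Zfp36 (1.53). The antioxidant list was 10 higher and 3 lower of 13, with a median of 0.59 (adjusted p = 0.0298, and adjusted p = 0.291 with an estimated correlation), and it did not pass after quantile normalization (0.0526). Prdx1, a peroxiredoxin, rose from 224 to 752 FPKM and Hmox1, a haem oxygenase, from 61.3 to 183. Inflammatory chemokines and cytokines were 10 higher and 4 lower of 15, with a median of 0.56 (adjusted p = 0.206), Il1b rising by 2.73 while the chemokines Ccl7 and Ccl2 changed by -3.89 and -3.48. TGF-beta signalling genes were 8 higher and 4 lower of 14, 8 and 5 when adjusted over the list alone, with a median of 0.42 (adjusted p = 0.181). The brown fat list, chosen because PRDM16 is known from that tissue, was 1 higher and 4 lower of 5, with a median of -1.37 (adjusted p = 0.0832), the member that rose being Prdm16 and Pparg, an adipocyte regulator, changing by -2.11.

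In the E2A-HLF cotransduction, 12 of 13 neutrophil granule genes and 9 of 14 monocyte genes rose with PRDM16, and 21 of 22 interferon response genes and 5 of 6 MHC class II genes fell. These 4 lists passed at the preset correlation and not with an estimated one (camera in limma, adjusted p = 0.251 or more). Mpo, the myeloperoxidase of neutrophil granules, measured 544 ± 25.4 FPKM (SD, n = 2) with PRDM16 and 43.3 ± 1.504 with PRDM16mut. Rtp4, an interferon-induced gene, measured 0.957 ± 0.179 against 25.5 ± 1.77 FPKM. Hoxa9 fell from 18.3 ± 0.660 to 5.73 ± 0.0440 FPKM, and Gfi1b rose from 5.91 ± 0.0569 to 13.1 ± 0.0987 FPKM.

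Prdm16 measured 52.9 ± 5.17 and 50.1 ± 9.26 FPKM with PRDM16 and PRDM16mut in the E2A-HLF cotransduction, a log2 difference of 0.09 that did not pass the test (limma, Benjamini-Hochberg adjusted p = 0.622). Hoxa9 changed by -1.52 (adjusted p = 8.80e-06), Gfi1b by 1.02 (adjusted p = 3.26e-05) and Meis1 by -0.51 (adjusted p = 4.71e-04). Of 11010 genes tested, 4822 passed (43.8%), 2499 higher and 2323 lower with PRDM16, and 633 of these changed at least 2-fold. The share of calls that were higher was 51.8%, but 44.7% after quantile normalization. It was 57.1% at an FPKM of at least 5 and 57.2% with the spread shared over all 12 libraries, both with fewer genes tested. The groups did not overlap for 73.7% of genes, where chance gives 33.3%. The median absolute log2 fold change of the called genes was 0.36.

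The genes that rose most in the E2A-HLF cotransduction were Stfa1, a stefin (log2 fold change 5.92, 792 ± 39.7 against 12.1 ± 0.131 FPKM, adjusted p = 1.80e-07 by limma), Vcam1, an adhesion molecule (5.33), Serpinb2 (5.27), Ms4a3, a gene of granulocyte precursors (5.12), Xlr (5.03), Stfa3 (4.94), S100a9, a calprotectin chain (4.69), and Car4 (4.56). Those that fell most were Rtp4 (-3.76), Oasl2 (-3.59), Foxred2 (-3.58), Ldhb (-3.54), Ifi27l2a (-3.54), Serpini1 (-3.33), Oas2 (-3.20) and Lgi1 (-2.91). Rtp4, Oasl2, Ifi27l2a and Oas2 belong to the interferon response list. Both rankings pass over clone names, predicted genes and small RNAs. Over all called entries the log2 fold change ran from -9.55 to 6.97.

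The neutrophil granule list was 12 higher and 0 lower of 13 in the E2A-HLF cotransduction, with a median log2 fold change of 3.62 (camera in limma, adjusted p = 1.92e-08, and adjusted p = 0.268 with an estimated correlation). Besides Mpo and Ms4a3, cathepsin G (Ctsg) rose from 10.0 to 237 FPKM and Cebpe, a regulator of granule genes, by 3.67. Monocyte and macrophage genes were 9 higher and 4 lower of 14, with a median of 1.04 (adjusted p = 0.0159, and adjusted p = 0.268 with an estimated correlation). Lysozyme (Lyz2) rose from 29.1 to 282 FPKM and Emr1, the macrophage marker F4/80, by 3.37. Mast cell, basophil and eosinophil genes were 6 higher and 1 lower of 10, 6 and 2 when adjusted over the list alone, with a median of 0.47 (adjusted p = 0.0472, and adjusted p = 0.304 with an estimated correlation). Hdc, the enzyme that makes histamine, and Cd200r3 rose by 3.21 and 2.63. The mast cell call was lost without replicate 2 of the PRDM16 group (adjusted p = 0.0594), and with the spread shared over all 12 libraries it (0.121) and the monocyte call (0.0535) were lost.

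Interferon response genes fell in the E2A-HLF cotransduction, 21 lower and 1 higher of 22, with a median log2 fold change of -1.89 (camera in limma, adjusted p = 1.01e-13, and adjusted p = 0.251 with an estimated correlation). Oas2 changed by -3.20 and Oas1a, another sensor of double-stranded RNA, by -2.18. MHC class II genes were 0 higher and 5 lower of 6, with a median of -1.31 (adjusted p = 3.02e-04, and adjusted p = 0.268 with an estimated correlation), H2-Aa going from 9.59 to 0.881 FPKM and Cd74 changing by -1.93. All 6 tested Hoxa genes fell, with a median of -1.01 (adjusted p = 1.41e-04, and adjusted p = 0.268 with an estimated correlation), Hoxa7 by -1.17 and Hoxa10 by -0.81. Stem and progenitor genes were 3 higher and 8 lower of 14, with a median of -0.42 (adjusted p = 0.00646, and adjusted p = 0.268 with an estimated correlation). The receptor kinase Flt3 went from 28.9 to 4.25 FPKM, and Egfl7, Procr and Sox4 changed by -1.44, -1.61 and -1.03.

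Inflammatory chemokines and cytokines were 10 higher and 1 lower of 12 in the E2A-HLF cotransduction, 11 and 1 when adjusted over the list alone, with a median log2 fold change of 0.52 (camera in limma, adjusted p = 1.41e-04, and adjusted p = 0.268 with an estimated correlation). The chemokine Ccl5 rose from 182 to 1598 FPKM and Il6 from 0.508 to 10.6. Immediate early genes were 9 higher and 1 lower of 12, with a median of 0.78 (adjusted p = 1.41e-04, and adjusted p = 0.268 with an estimated correlation), with Fosb, Fos, Egr1 and Jun higher by 2.30, 2.08, 1.41 and 1.39. The Myc and ribosome biogenesis list was 8 higher and 1 lower of 18, with a median of 0.15 (adjusted p = 0.0238, and adjusted p = 0.351 with an estimated correlation). Srm, the spermidine synthase, rose by 0.62. The list did not pass after quantile normalization (adjusted p = 0.107), nor without replicate 1 (0.0667) or replicate 2 (0.0511) of the PRDM16 group, nor with the replicate number as a block (0.0513), nor with the spread shared over all 12 libraries (0.0520).

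The other lists did not pass in the E2A-HLF cotransduction. MLL fusion targets outside Hoxa were 4 higher and 7 lower of 13, 5 and 7 when adjusted over the list alone, with a median log2 fold change of -0.20 (camera in limma, adjusted p = 0.313), Mef2c changing by -1.29 and Runx1 by 0.65. The megakaryocyte list was 7 higher and 5 lower of 12, with a median of 0.22 (adjusted p = 0.508), F2r and the integrin Itga2b rising by 2.17 and 1.81 and Selp changing by -1.18. Erythroid genes were 4 higher and 2 lower of 15, with a median of 0.03, a mean of -0.09 and a camera direction below 0 (adjusted p = 0.964), and Car2 went from 152 to 47.1 FPKM. The p53 target list was 8 higher and 2 lower of 16, with a median of 0.16 (adjusted p = 0.0548), Perp rising by 2.48. It passed without a filter on low values (0.0242), without small RNAs (0.0454), and without replicate 1 of the PRDM16 group (0.0454) or replicate 1 (0.0452) or 2 (0.0362) of the mutant group. T and NK cell genes were 2 higher and 1 lower of 3, with a median of 0.32 (adjusted p = 0.719) and fry pointing below 0. Cell division genes were 3 higher and 2 lower of 25, 3 and 0 when adjusted over the list alone, with a median of 0.06 (adjusted p = 0.404). TGF-beta signalling was 6 higher and 5 lower of 13, with a median of 0.00 (adjusted p = 0.952), Tgfbr2 and Id1 rising by 0.95 and 0.92. The antioxidant list was 4 higher and 3 lower of 13 (median 0.07, adjusted p = 0.417), and brown fat genes were 2 higher and 0 lower of 4 (median 0.53, adjusted p = 0.102, and 0.0462 and 0.0490 without replicate 1 and 2 of the mutant group). The B cell and stromal lists had 1 tested member each, which fell in the first list and rose in the second (Vcam1).

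**Figure D2:**
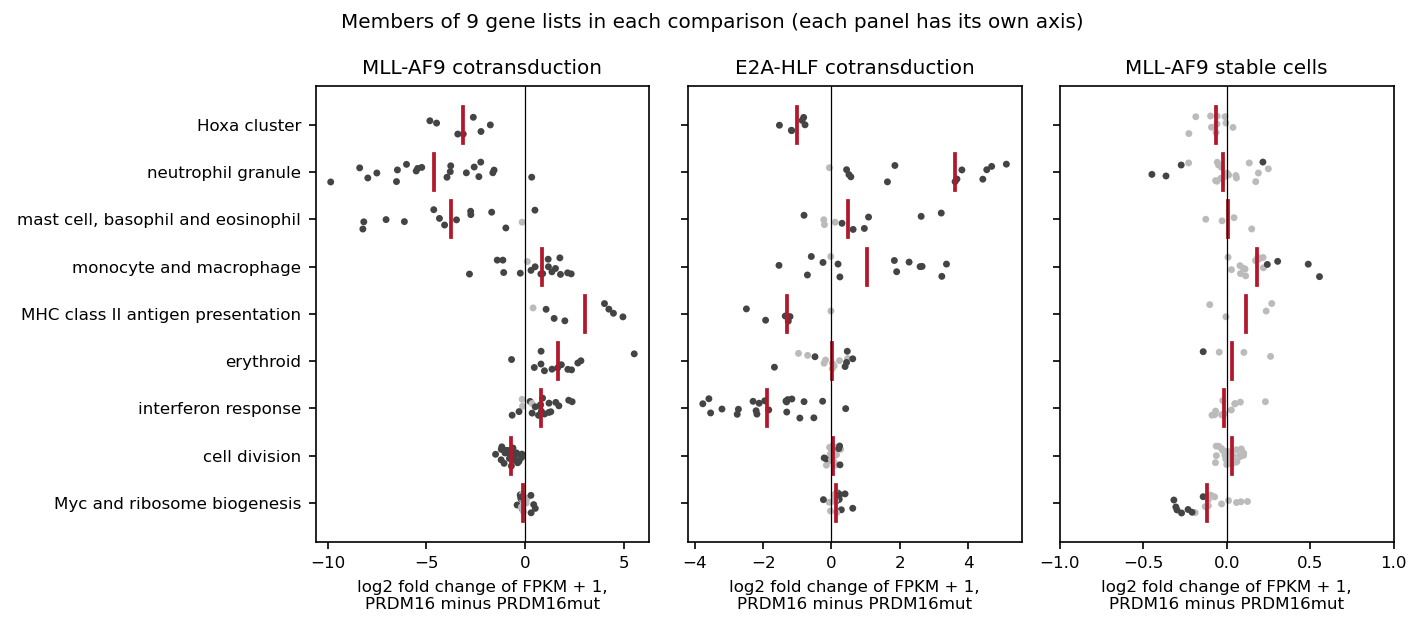
Log2 fold change of FPKM + 1, PRDM16 minus PRDM16mut, of the members of 9 gene lists in each experiment, with a dot per gene (dark where its limma adjusted p was under 0.05) and a red bar at the list's median. The neutrophil granule median lies at -4.60 in the MLL-AF9 cotransduction, 3.62 in the E2A-HLF cotransduction and -0.02 in the stable cells.

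In the MLL-AF9 stable cells, PRDM16 and PRDM16mut differed in few genes and by small amounts. Of 16 monocyte genes 4 were called, all slightly higher with PRDM16, such as F13a1, a coagulation factor chain of monocytes, at 98.8 ± 0.0339 FPKM (SD, n = 2) against 66.9 ± 1.04. Of 18 Myc and ribosome biogenesis genes 7 were called, all slightly lower, such as Cad, a pyrimidine synthesis enzyme, at 20.5 ± 0.167 against 25.8 ± 1.13 FPKM. Neither list passed with an estimated correlation (camera in limma, adjusted p = 0.731 and 0.735). Cdkn2a, the locus of the p16 and p19 cell cycle inhibitors, rose from 11.4 ± 0.0382 to 19.5 ± 1.27 FPKM, and Ppic, a cyclophilin, fell from 11.1 ± 1.53 to 3.20 ± 0.356 FPKM.

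Prdm16 measured 78.9 ± 1.46 FPKM with PRDM16 and 91.8 ± 3.92 with PRDM16mut in the stable cells, a log2 difference of -0.22 (limma, Benjamini-Hochberg adjusted p = 0.0414). Hoxa9 was at 78.8 ± 0.0919 and 82.1 ± 1.33 FPKM (log2 -0.06, adjusted p = 0.240) and Meis1 at 14.4 ± 0.444 and 15.8 ± 0.180 FPKM (-0.12, adjusted p = 0.108), neither past the threshold. Gfi1b stayed below the expression filter at 0.396 and 0.361 FPKM and was not tested. Of 10580 genes tested, 673 passed (6.36%), 444 higher and 229 lower, and 34 of these changed at least 2-fold. Without small RNAs, a setting chosen after the data were seen, 1361 passed and 4 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 3042. The median absolute log2 fold change of the called genes was 0.24, and the groups did not overlap for 60.6% of genes, where chance gives 33.3%. The share of calls that were higher was 66.0%, but 50.7% after quantile normalization and 53.3% after median-ratio scaling. The count fell to 41 without a filter on low values, to between 65 and 139 when 1 library was left out, and rose to 1499 with a robust prior.

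The genes that rose most in the stable cells were Glod5 (log2 fold change 0.76, limma adjusted p = 0.0481), Cdkn2a (0.73, adjusted p = 0.00397), Tmsb15l (0.68), Dlk1, a Notch family ligand (0.66), Cth, a cysteine synthesis enzyme (0.64), Saa3 (0.62), Itm2a (0.61) and Mt2, a metallothionein (0.61). Those that fell most were Ppic (-1.52), Clec2g (-1.27), Xlr (-1.24, adjusted p = 1.19e-04), Hspa2 (-0.81), Krtcap3 (-0.72), Lin28b, an RNA-binding protein of fetal cells (-0.69), Slc22a3 (-0.64) and Clec11a (-0.52). Both rankings pass over clone names, predicted genes and small RNAs. Over all called entries the log2 fold change ran from -8.25 to 8.23, with 15 higher and 19 lower by at least 2-fold. Of the 35 named genes called in the stable cells, 6 passed in the same direction under every setting run for single genes, which leaves out the minimum change of 2-fold. These were Cth, Clec2g, Xlr, Hspa2, Slc22a3 and F13a1, and only Clec2g and Xlr changed at least 2-fold. The other 29 lost their call under at least 1 setting, Prdm16, Cdkn2a and Ppic among them.

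Monocyte and macrophage genes were 4 higher and 0 lower of 16 in the stable cells, 8 and 0 when adjusted over the list alone, with a median log2 fold change of 0.18 (camera in limma, adjusted p = 6.62e-05, and adjusted p = 0.731 with an estimated correlation). F13a1, Cd14, Lyz1 and Lyz2 rose by 0.56, 0.49, 0.30 and 0.24. The Myc and ribosome biogenesis list was 0 higher and 7 lower of 18, 2 and 11 when adjusted over the list alone, with a median of -0.12 (adjusted p = 5.23e-05, and adjusted p = 0.735 with an estimated correlation). Cad, Nolc1, Polr1b and Srm changed by -0.32, -0.30, -0.27 and -0.21. Fry, also in limma, called the monocyte list and the inflammatory list (adjusted p = 0.0295 for each) and not the Myc list (0.130).

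No other list passed by camera in the stable cells as set in advance. Neutrophil granule genes were 1 higher and 3 lower of 20, 3 and 4 when adjusted over the list alone, with a median of -0.02 (camera in limma, adjusted p = 0.385), Lcn2 higher by 0.22 and Mpo, Camp and Chi3l3 changing by -0.45, -0.36 and -0.27. Inflammatory genes were 2 higher and 0 lower of 13, 3 and 1 when adjusted over the list alone, with a median of 0.10 (adjusted p = 0.0740), the chemokines Ccl9 and Ccl3 rising by 0.36 and 0.23. This list passed at an FPKM of at least 5 (0.0414) and, over fewer members, with the spread shared over all 12 libraries (0.0297). The antioxidant list had 2 higher and 0 lower of 13 (median 0.04, adjusted p = 0.450), Slc7a11 and Hmox1 rising by 0.34 and 0.28. The p53 targets had 1 higher, Cdkn1a at 0.35, and 1 lower, Aen at -0.21, of 15 (2 and 1 when adjusted over the list alone, median 0.04, adjusted p = 0.504). None of the 10 Hoxa genes (median -0.06, adjusted p = 0.0740), 11 other MLL targets (1 higher when adjusted over the list alone, median -0.03, adjusted p = 0.222), 25 cell division genes (median 0.03, adjusted p = 0.665) or 10 TGF-beta genes (1 higher when adjusted over the list alone, median 0.08, adjusted p = 0.385) passed over all genes. At an unadjusted p under 0.05 these 4 lists had 2, 5, 2 and 1 members.

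Interferon response genes gave 0 calls of 12 in the stable cells, with a median log2 fold change of -0.02, a mean of 0.01 and a camera direction below 0 (adjusted p = 0.871). Also with 0 calls were the 4 mast cell members (median 0.01, camera direction below 0, adjusted p = 0.966) and the 4 MHC class II members (2 higher and 1 lower when adjusted over the list alone, median 0.12, camera adjusted p = 0.902). At an unadjusted p under 0.05 these 3 lists had 1, 0 and 3 members. Stem and progenitor genes had 1 call, higher, of 8 (1 and 3 when adjusted over the list alone, median -0.10, adjusted p = 0.501), with fry pointing above 0. Erythroid genes had 1 call, lower, of 4 (1 and 1 when adjusted over the list alone, median 0.03, camera direction below 0, adjusted p = 0.999). The megakaryocyte list had 1 of 3 higher (median 0.16, adjusted p = 0.504), the immediate early list 1 of 10 higher (median 0.11, adjusted p = 0.222) and the brown fat list 1 of 5 lower, which is Prdm16 (1 and 1 when adjusted over the list alone, median 0.07, adjusted p = 0.966). The B cell, T and NK cell and stromal lists had 1, 2 and 2 tested members, with 0 calls over all genes by limma, and 0, 0 and 1 at an unadjusted p under 0.05.

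The difference between PRDM16 and PRDM16mut was not the same in the experiments for most genes. Neutrophil granule genes had a median difference of 7.38 on the log2 scale between the E2A-HLF and MLL-AF9 cotransductions (13 of 13 members above, camera in limma adjusted p = 2.61e-10, and adjusted p = 0.0499 with an estimated correlation). MHC class II genes had a difference of -4.35 (0 above and 4 below of 4, adjusted p = 5.39e-04, and adjusted p = 0.112 with an estimated correlation). Interferon response genes differed by -2.14 (0 above and 12 below of 12, adjusted p = 4.26e-07, and adjusted p = 0.0499 with an estimated correlation). Over all 9488 genes tested in every table, the effect differed for 6778 genes (71.4%) between the cotransductions by limma, and for 4951 of these the effects had opposite signs. Between the stable cells and the MLL-AF9 cotransduction it differed for 6071 genes (64.0%).

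The Hoxa cluster fell in both cotransductions, less so with E2A-HLF, where the effect lay 2.11 above that with MLL-AF9 in the median of 6 genes (camera in limma, adjusted p = 5.33e-04, and adjusted p = 0.0499 with an estimated correlation). Hoxa9 alone differed by 3.31 between the cotransductions and by 4.77 between the stable cells and the MLL-AF9 cotransduction. Meis1 differed by -1.61 and -1.22, rising in the MLL-AF9 cotransduction only among the 3 experiments. Cell division genes, lower in the MLL-AF9 cotransduction, differed by 0.79 with E2A-HLF (23 above and 0 below of 25, camera in limma adjusted p = 7.46e-07, and adjusted p = 0.0716 with an estimated correlation). In the stable cells they differed by 0.69 (24 above and 0 below, adjusted p = 1.13e-08, and adjusted p = 0.0526 with an estimated correlation).

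Genes called in both cotransductions moved more often in opposite directions than in the same one. Of 10006 genes tested in both, 980 were called in the same direction and 2267 in opposite directions, which makes 30.2% in the same. Higher with MLL-AF9 and lower with E2A-HLF were 1166 genes, where independent calls would give 686 (Fisher's exact test, Benjamini-Hochberg adjusted p = 1.96e-134), and the reverse held for 1101, where they would give 772 (adjusted p = 1.19e-58). Across genes, which are not independent replicates, the fold changes had a Pearson correlation of -0.35 and a Spearman correlation of -0.30. Between the MLL-AF9 cotransduction and the stable cells, 174 genes were higher in both where 128 would be by chance (adjusted p = 1.60e-06), 92 were lower in both where 74.7 would be (0.0159), and the correlations were 0.01 and 0.16. In opposite directions there were 43 higher in the first and lower in the second where 68.0 would be (adjusted p = 2.04e-04), and 137 the other way (0.748). Between E2A-HLF and the stable cells, 162 genes were higher in both where 90.9 would be by chance (Fisher's exact test, adjusted p = 1.00e-15) and 21 lower in both where 38.3 would be (0.00150), with correlations of 0.04 and -0.12. But 88 genes were higher with E2A-HLF and lower in the stable cells where 49.4 would be (6.20e-09), and 83 the other way (0.103), so 183 moved the same way and 171 in opposite ways. At an adjusted p under 0.01 the balance changed, to 16 the same and 15 opposite for the MLL-AF9 cotransduction and the stable cells and 22 and 8 for E2A-HLF and the stable cells. The overlaps with the stable cells rest on the calls there, which fell from 673 to between 65 and 139 when 1 library was left out. Fisher's test counts genes as independent units, which they are not. None of its p-values here measures a spread between libraries.

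**Figure D3:**
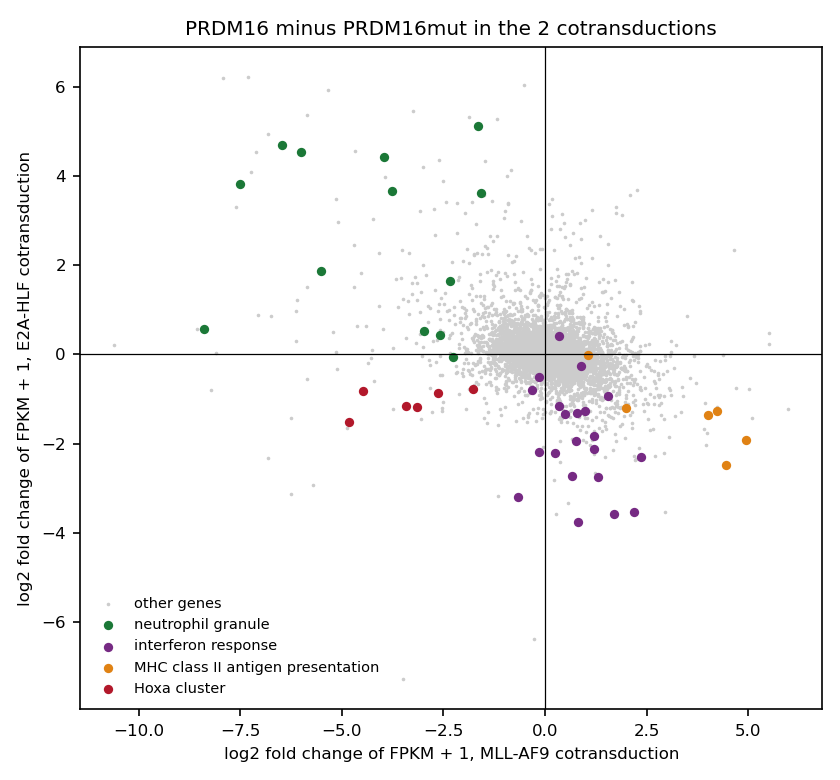
Log2 fold change of FPKM + 1, PRDM16 minus PRDM16mut, of each gene in the E2A-HLF cotransduction against that in the MLL-AF9 cotransduction, with 4 gene lists in colour. Neutrophil granule genes lie mostly at the upper left and MHC class II genes mostly at the lower right, and all Hoxa genes tested in both fell in both.

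A small group of genes changed the same way in all 3 experiments, 57 higher and 4 lower with PRDM16, where 40.5 in all would if the calls were independent. With the labels of E2A-HLF exchanged 100 would (37.8 if independent), with those of the MLL-AF9 cotransduction 80 (41.6), and with those of the stable cells 29 (38.2). The count of 61 lies above only the last of these, so it does not by itself mark a shared response to PRDM16. The excess was not tested, and it rests on the same calls in the stable cells. The 8 of largest mean change were all higher. Bcl2a1b, an antiapoptotic gene, rose by 2.08, 3.58 and 0.50 on the log2 scale in the MLL-AF9 cotransduction, the E2A-HLF cotransduction and the stable cells. Lyz2 and Lyz1, the lysozymes, rose by 1.16, 3.23 and 0.24 and by 1.35, 2.65 and 0.30. Cd14, the endotoxin co-receptor, rose by 0.88, 2.60 and 0.49, and the transcription factor Klf2 by 1.71, 1.67 and 0.39. Cd52, Plek and Lgals3 followed, with 0.68, 1.43 and 1.85 in the MLL-AF9 cotransduction. Lyz1, Lyz2 and Cd14 are in the monocyte list, and each lost its call in the stable cells under at least 1 setting.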

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

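The tests of whether the effect of PRDM16 differs between experiments were planned, while all tests of explanations given here were chosen after the results had been seen. Each gene below passed a test of the difference itself, in 1 limma fit of all 12 libraries, and each list did by camera at the preset correlation. A positive difference means that PRDM16 minus PRDM16mut lay higher than in the MLL-AF9 cotransduction.

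Between the E2A-HLF and MLL-AF9 cotransductions the effect differed for 6778 of 9488 genes, and between the stable cells and the MLL-AF9 cotransduction for 6071. Of the gene lists, the median log2 difference in E2A-HLF was 7.38 for neutrophil granule genes, 2.84 for mast cell, basophil and eosinophil genes, 2.11 for the Hoxa cluster, 0.79 for cell division and 0.73 for MLL fusion targets outside Hoxa. It was -4.35 for MHC class II genes, -2.14 for interferon response genes, -1.40 for stem and progenitor genes, -0.44 for p53 targets and -0.33 for antioxidant genes. In the stable cells it was 3.79 for neutrophil granule genes, 3.23 for the Hoxa cluster, 1.27 for mast cell genes, 0.69 for cell division and 0.57 for the other MLL fusion targets. It was -3.03 for MHC class II genes, -0.92 for immediate early genes, -0.57 for p53 targets and -0.42 for antioxidant genes. With an estimated correlation only the neutrophil, Hoxa and interferon differences passed in E2A-HLF (camera adjusted p = 0.0499 each), and the others lay at 0.0716 (cell division) to 0.233 (antioxidant). In the stable cells only the neutrophil and Hoxa differences passed so (0.0462 each), and the others lay at 0.0526 (cell division) to 0.230 (immediate early).

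Single genes with the largest differences in E2A-HLF were the stefins Stfa3 (11.75), Stfa2l1 (11.64) and Stfa1 (11.25), Elane (11.33) and S100a9 (11.16), and, on the other side, Cd74 (-6.87), the beta-glucan receptor Clec7a (-5.76), Ifi27l2a (-5.73), H2-Ab1 (-5.49) and Ube2l6 (-4.57). In the stable cells they were Ngp (8.33), Stfa2 (7.85), Elane (7.46) and Stfa2l1 (7.16), and Cd74 (-4.71), H2-Ab1 (-3.96), Clec7a (-3.95), Mfge8 (-3.69) and Ass1 (-3.19). Rn45s had a fitted difference of 10.69 in the stable cells, which is no bound, since it is listed at 0 in both PRDM16 libraries of the MLL-AF9 cotransduction. Whether those libraries were processed like the others is not given in the sources used here. Of the genes fixed in advance, Prdm16 differed by -1.63 in E2A-HLF and -1.93 in the stable cells, Hoxa9 by 3.31 and 4.77, and Meis1 by -1.61 and -1.22.

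In the MLL-AF9 cotransduction, Hoxa, neutrophil and mast cell genes were low and MHC class II genes high with PRDM16. A few abundant transcripts of the mutant libraries, such as S100a8, would shift all other genes up with PRDM16. Such a shift could not lower Hoxa or mast cell genes. The neutrophil granule list kept a median of -4.65 after quantile normalization (camera adjusted p = 1.57e-11), but it holds S100a8 itself, so it cannot decide. For the genes that rose, the MHC class II median stayed at 3.01 (camera adjusted p = 9.5e-05), which argues against a shift. Without that normalization neither list passed with an estimated correlation (camera adjusted p = 0.198 and 0.329). A lower share of neutrophil-type cells alone would have raised the markers of all other types, but mast cell genes fell, with a median of -3.78 and an upper quartile of -1.97 (14 genes, camera adjusted p = 6.02e-07, and 0.198 with an estimated correlation). The level of Prdm16 transcript, 3.41-fold higher with PRDM16 than with PRDM16mut, could contribute and cannot be told apart from the mutation in this experiment, although the Hoxa median of -1.01 in E2A-HLF came with a log2 difference in Prdm16 of 0.09 that did not pass the test. A change of cell types or of their state through PRDM16 is a biological alternative and was not tested. Nor was a difference in processing of the PRDM16 libraries, where Rn45s is listed at 0. Transcripts of both fusion partners were also lower with PRDM16, Mll1 at a mean of 2.6 against 6.5 FPKM and Mllt3 at 1.0 against 3.0. Whether they include the introduced fusion is not given, so its level was not tested. In the E2A-HLF libraries, which did not receive MLL-AF9, Mll1 was at 5.84 to 7.75 FPKM and Mllt3 at 3.29 to 4.33. The levels with PRDM16mut thus show no excess over cells without this fusion.

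The neutrophil, interferon and MHC class II lists moved in opposite directions in the cotransductions. Scaling within each table does not account for it, since all 3 lists kept opposite medians, past the threshold in both at the preset correlation, after quantile normalization. Without that normalization none of the 3 passed in either cotransduction with an estimated correlation (camera adjusted p = 0.198 or more). Exchanged labels in 1 cotransduction might give such a pattern, and the values do not settle it. In all 3 experiments 61 genes were called the same way, against 100 or 80 with the labels of E2A-HLF or of the MLL-AF9 cotransduction exchanged. These counts follow from the opposite movement itself and cannot decide. If PRDM16 acts alike on them, an exchange would set Gfi1b and the Hoxa cluster apart as labelled. But Gfi1b was higher and all tested Hoxa genes, 7 and 6, were lower with PRDM16 in both. This argues against an exchange only under that assumption, which was not tested. The stable cells do not help, since none of their 10 tested Hoxa genes was called and Gfi1b was not tested there. Among genes also called in the stable cells, the odds ratio between the directions was 2.71 for the MLL-AF9 cotransduction and 0.467 for E2A-HLF (Fisher's exact test, adjusted p = 6.21e-06 and 0.00541). It compares the odds of being higher in the stable cells between genes higher and lower in the cotransduction. It is no share of genes moving the same way, which with E2A-HLF were 183 against 171 opposite. It rests on the 673 calls in the stable cells, which were 278 without a trend in the prior and 1499 with a robust prior. Its p-values count genes as independent units, which they are not. At an adjusted p under 0.01 same and opposite numbered 16 and 15 for the MLL-AF9 cotransduction, and 22 and 8 for E2A-HLF. That the fusion oncogene sets the direction of the effect is the biological alternative that the design names, and it was not tested apart from the experiment it was used in.

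The stable cells showed few and small changes. A larger spread between replicates is excluded for the typical gene by the median standard error of the log2 fold change. It was 0.0428 in the stable cells against 0.0672 and 0.0581 in the cotransductions of MLL-AF9 and E2A-HLF. It does not cover the spread of part of the genes, since 673 calls became 1361 without small RNAs and 1499 with a robust prior. A lack of Prdm16 transcript from any source is excluded too. Its lowest level was 77.9 FPKM in the stable cells, against a highest level of 30.1 in the mutant libraries of the MLL-AF9 cotransduction. The protein was not measured and the levels come from separate tables. A lack of the introduced copy is not excluded. The values do not separate it from the cells' own gene, and no group without either form gives a baseline. Another origin of the cells may matter and cannot be told apart from the experiment, since Xist, a transcript of female cells, was at 46.5 FPKM or more in all 4 stable libraries and at 0.0641 or less in the other 8. The timing of PRDM16, given to cells already transformed or together with the oncogene, is the biological alternative and was not tested.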

How the results depend on the processing

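One of the settings, without small RNAs, was added after the data were seen. Over the settings run, 3089 of 3246 values of named genes kept direction and side of the threshold. So did 799 of 851 list results by camera at the preset correlation, and 140 of 161 counts stayed within 1.5 times. The 851 leave out fry and camera with an estimated correlation, and the minimum change of 2-fold was run for counts only. No list past the threshold turned direction, and the genes that did, Lck in the MLL-AF9 cotransduction and Prdm16 in E2A-HLF, had not passed. The count of called genes ran from 5259 to 8689 when 1 library was left out of the MLL-AF9 cotransduction, 3753 to 4020 in E2A-HLF and 65 to 139 in the stable cells (74 and 65 without PRDM16 replicates 1 and 2, 101 and 139 without mutant replicates 1 and 2), a lone library being assumed to vary like the other group. Called lists ran from 11 to 12, 8 to 12 and 2 to 2, and the differences from 6266 to 6972 and from 5483 to 6461. At a change of at least 2-fold the counts were 1720, 633 and 34, and 1677, 603 and 4 without small RNAs. In the stable cells the count was 41 without a filter on low values, where more genes are tested, 1499 with a robust prior, 278 without a trend in the prior, 299 with the spread shared over all 12 libraries and 1361 without small RNAs. With an estimated correlation camera called 0 lists in each comparison, with 4, 2 and 1 at an unadjusted p under 0.05, while fry called 18, 15 and 2. The Hoxa list of the MLL-AF9 cotransduction lost its call so at an estimated correlation of -0.147, below the preset value. At an adjusted p under 0.01, genes called the same and opposite ways numbered 513 and 1344 for the cotransductions, 16 and 15 for MLL-AF9 cotransduction and stable cells, and 22 and 8 for E2A-HLF and stable cells. The labels do not say that replicate numbers pair samples, and with them as a block the counts were 7812, 4354 and 664.

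Lists that turned direction by camera, none past the threshold, had these median log2 fold changes. With the spread shared over all 12 libraries they were -0.92 (megakaryocyte, MLL-AF9 cotransduction), 0.20 (megakaryocyte, E2A-HLF), 0.0289 (erythroid, stable) and 0.0412 (brown fat, stable). Without a filter they were 0.0282 (erythroid) and -0.00403 (T and NK cell) in E2A-HLF, and -0.0203 (megakaryocyte), 0.0427 (mast cell) and -0.00384 (MHC class II) in the stable cells. Quantile normalization gave -0.00516 (erythroid) and -0.0245 (cell division) in E2A-HLF and 0.00758 (erythroid) and 7.95e-04 (cell division) in the stable cells, and median-ratio scaling 0.0148 and 0.0152 for erythroid genes. The stable erythroid median was 0.0289 also at an FPKM of at least 5, with the replicate block and without small RNAs. Leaving out 1 library gave -0.00268 to 0.31 for Lck (MLL-AF9), -0.10 to 0.27 for Prdm16 and -0.0336 to 0.0737 for TGF-beta genes (E2A-HLF), and in the stable cells -0.026 to 0.0838 (erythroid), -0.00719 to 0.0215 (mast cell), -0.0243 to -0.00706 (interferon) and -0.0538 to 0.15 (brown fat). Except where fewer genes or libraries were used, the cause was not tested. Total depth is unknown, since the tables hold no counts, but steps between low values put replicate 2 of the PRDM16 group of the MLL-AF9 cotransduction at 1.63 times the depth of replicate 1, against 0.916 to 1.17 in the other groups. How far this limits low values was not tested, and genes under the filter, such as Gfi1b in the stable cells, were not tested.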

Other observations

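The genes and families in this part were chosen after their values had been seen, and levels compared across experiments come from separate tables. Gfi1, the myeloid relative of Gfi1b and a repressor needed for neutrophils, was at 1.23 and 2.01 FPKM with PRDM16 and at 88.6 and 88.8 with PRDM16mut in the MLL-AF9 cotransduction. In E2A-HLF it averaged 27.8 FPKM against 35.4, and in the stable cells 60.1 against 62.4. S100a8, the partner of S100a9 in calprotectin, was the most abundant transcript of the mutant libraries of the MLL-AF9 cotransduction, at 29620 and 28541 FPKM, and stood at 503 and 402 with PRDM16. The stefin Stfa1 was at 3835 and 3836 FPKM against 110 and 81.1. The ferritin chains went the other way, Fth1 at 7680 and 7544 FPKM with PRDM16 against 1524 and 1516, and Ftl1 at 13092 and 13903 against 6053 and 6042. Galectin 1, Lgals1, was at 1875 and 1913 against 500 and 491 FPKM.

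Families of symbols that open with the same letters, with at least 10 tested members, were scanned with camera, which called 6 of 110, 4 of 106 and 3 of 101 in the MLL-AF9 cotransduction, E2A-HLF and the stable cells. None was called with an estimated correlation (adjusted p = 0.936, 0.986 and 0.988 at the lowest). Ribosomal proteins of the large subunit (Rpl) were 41 higher and 1 lower of 47 in the MLL-AF9 cotransduction, with a median log2 fold change of 0.42 that was 0.15 after quantile normalization (camera in limma, adjusted p = 1.25e-05). Those of the small subunit (Rps) were 33 higher and 4 lower of 42, with a median of 0.43 that was 0.12 after quantile normalization. Subunits of respiratory complex I (Ndufa) were 13 of 13 higher, with a median of 0.52 (adjusted p = 0.0058). Centrosomal Cep genes were 1 higher and 20 lower of 28 (median -0.35), nuclear pore Nup genes 1 and 15 of 20 (-0.34), and the replication licensing Mcm genes 0 and 9 of 10 (-0.44). In E2A-HLF, Trim genes, many of them interferon-inducible, were 0 higher and 19 lower of 36 (median -0.18, adjusted p = 0.00195), and caspases were 1 higher and 7 lower of 10 (-0.38). Nup genes were 11 higher and 0 lower of 19 there (0.17), and zinc finger Zfp genes 20 higher and 81 lower of 267 (-0.10, adjusted p = 0.0193). In the stable cells the 3 families held few called genes, with Ddx helicases 0 higher and 2 lower of 33 (-0.06, adjusted p = 0.00263), Nup genes 0 and 3 of 20 (-0.04) and Rpl genes 0 and 0 of 47 (0.08). Quantile normalization moved the medians of Nup genes to 0.10 in E2A-HLF and -0.07 in the stable cells, and that of Rpl genes in the stable cells to 0.03.

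Transcripts of the fusion partners were measured in all libraries, but whether reads of the introduced fusions are counted for them is not given in the sources used here. Tcf3, the gene of E2A, was at 166 to 203 FPKM in the 4 E2A-HLF libraries and at 19.3 to 25.7 elsewhere, and Hlf was at 14.9 to 17.0 there. Mll1 was at 2.41 and 2.80 FPKM with PRDM16 and at 6.44 and 6.65 with PRDM16mut in the MLL-AF9 cotransduction, and Mllt3, the gene of AF9, was at 1.03 and 0.989 against 3.26 and 2.67. In the E2A-HLF libraries, which did not receive MLL-AF9, Mll1 was at 5.84 to 7.75 FPKM and Mllt3 at 3.29 to 4.33. In the stable cells they were at 5.95 to 6.91 and at 2.74 to 2.94. Unlike Tcf3, Mll1 and Mllt3 were thus not higher where their fusion was introduced. Mecom, a relative of Prdm16, was listed at 0 in all 12 libraries. Transcripts of the Y chromosome were present in the cotransductions and not in the stable cells, with Ddx3y at 8.68 to 24.8 FPKM against 0.0297 or less. Among them Eif2s3y was at 33.2 and 28.8 FPKM with PRDM16 against 5.05 and 5.07 with PRDM16mut in the MLL-AF9 cotransduction, and at 21.3 and 20.1 against 44.9 and 47.4 in E2A-HLF.

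Over 11480 genes, which are not independent replicates, the mutant libraries of the MLL-AF9 cotransduction correlated with the stable libraries at a Pearson r of 0.917 to 0.921, and the PRDM16 libraries at 0.833 to 0.839. In the E2A-HLF cotransduction the order was the reverse. Its PRDM16 libraries correlated with the stable libraries at 0.886 to 0.892, and its mutant libraries at 0.849 to 0.858. No explanation was tested for any of these values.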
